A study of Mus musculus with 2 samples.

How the data were processed

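DNase-seq maps open chromatin by sequencing the ends of fragments that the enzyme DNase I cuts from nuclei, since DNA that is not wrapped tightly in nucleosomes is cut more often. The samples were neural tube, the embryonic precursor of the brain and spinal cord, from mouse embryos of the B6NCrl strain at 11.5 days of development, with male and female embryos pooled. Per the labels there was 1 group with 2 biological replicates, taken as separate tissue samples that carry the same donor label, each sequenced as 1 library and named here replicate 1 and replicate 2. Both libraries were run on more than 1 model of sequencer, and the labels name an additional model for replicate 2. The labels define no second group, so every comparison was made within a library and then set beside the other library. With 2 libraries of 1 group no test across samples was run, and the p-values below treat genes or peaks as units, which are not independent replicates.

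Per the deposited files, the authors called peaks and hotspots separately in each library on the mm10 build of the mouse genome, without pooling the replicates. The aligner, the caller, its version and its threshold are not given in the sources used here. A peak was a window of 150 bp with a score that the authors deposited as a whole number. This score never exceeded 150, its meaning is not given in the sources used here, and it was used only to rank or filter peaks within a list. A hotspot was a broader region for which the authors deposited a −log10 q-value, which ran from 1.30 to 6 and then jumped to 100. The depth of sequencing is unknown, because the files hold no read counts, and no interval that needs the depth was computed.

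Rows that repeated the position of another row were removed, 45 in replicate 1 and 22 in replicate 2. The GRCm38.p6 genome sequence and the GENCODE vM21 annotation were used, and mm10 is the same assembly. Every deposited region on the main chromosomes ended within the length of its chromosome in that sequence. The annotation gave 21853 protein-coding genes with 54361 transcription start sites (TSSs). A gene had a promoter peak when a peak overlapped the 500 bp to either side of any of its TSSs. A peak was distal when its centre lay more than 1 kb from every protein-coding TSS, and it was assigned to the gene with the nearest TSS. The territory of a gene was the length of genome closer to its TSSs than to those of any other gene.

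Overlap of peaks required 1 bp, and hotspots were compared by bases in both lists over bases in either list. Chance overlap came from 20 shuffles of the regions over their own chromosomes outside assembly gaps. A total of 17 lists of genes and 18 gene families, 35 sets in all, were fixed before the data were examined, as were 34 consensus motifs and the rules for naming genes. Promoter peaks in a set were compared with the 19121 genes in no set by Fisher's exact test, two-sided. Distal peaks per gene were compared with 10000 random lists from the same deciles of territory length by a permutation test, two-sided, whose smallest possible p was 0.0002. Both were adjusted by the Benjamini-Hochberg method over sets and libraries, and a set was called when the adjusted p was under 0.05 in the same direction in both libraries.

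Motif matches on either strand in distal and in promoter peaks were compared with as many random windows of 150 bp outside the hotspots of both libraries, matched in bins of 2 percentage points of GC content, by Fisher's exact test with Benjamini-Hochberg adjustment. A motif was called when the adjusted p was under 0.05 and the ratio of shares was at least 1.5 in both libraries, and a motif with no match in the windows counted as above that ratio, a rule set after REST was seen to have none at promoters. Windows came from 4000000 random positions. GC-rich windows are scarce, so in the comparison with promoter peaks 36.5% and 40.1% of windows came from bins drawn with replacement, against 0.664% and 1.58% for distal peaks. Intervals of ratios are exact binomial 95% intervals and cover counting error only, as does the 95% interval of the odds ratio of Hox peaks, by the method of Woolf.

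The genes named are the 3 with the most distal peaks in each list, those that depart from the rest of their list at the promoter in both libraries, up to 5 by symbol, the 10 genes and the 10 distal peaks that lead the genome, the genes nearest to strong peaks found in 1 library only, and the Hox genes by cluster. Some genes that this rule names are not reported here. Genes with a promoter peak in 1 library only were named after their values were seen. A strong peak was in the top 10% of its list by score. Lists of markers for neural crest and peripheral glia, mesoderm and connective tissue, endothelium, erythroid cells, myeloid cells and microglia, late glia, liver, heart and striated muscle and lymphocytes stood for other cell types. In the erythroid list 17 of 18 symbols were found among the annotated genes. Close paralogs such as Hba-a1 and Hba-a2 share sequence, so the peaks of such genes are uncertain.

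The functions were tested on simulated data. A planted overlap of 60% of 20000 peaks came out as 60%, and matches planted for the 34 motifs were found for 100% of motifs. Of 200 simulated lists of 20 genes with all promoters open, 100% were called, against 37.5% of lists with 90% of promoters open and 0% of lists with the share of other genes. For distal peaks 99.5% of lists with a 3-fold excess, 67.5% with a 2-fold excess and 20.5% with a 1.5-fold excess were called, and 0% without an excess. These functions were run on the deposited data before the simulated data. Alternatives covered the overlap required, the score threshold, equal list lengths, autosomes, hotspots in place of peaks, promoter windows, 1 TSS per gene, GC-matched lists, other definitions of distal peaks, other motif backgrounds and each library on its own, with lists moved as blocks along the genome and windows matched on CpG count as alternatives chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.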

Results

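Open chromatin was mapped by DNase-seq in neural tube of mouse embryos at 11.5 days of development, in 2 replicate libraries of 1 group. Replicate 1 held 199653 peaks and replicate 2 held 154324 peaks of 150 bp. Hotspots covered 78.5 Mb, or 2.97% of the sequenced genome, in replicate 1 and 50.9 Mb, or 1.92%, in replicate 2. The median score of a peak, as the authors gave it, was 45 in replicate 1 and 26 in replicate 2. Scores were not compared between the lists, and the sequencing depth of the libraries is unknown.

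The extent to which both libraries opened the same regions was examined by overlap. Of the peaks in replicate 1, 52.6% overlapped a peak in replicate 2. Of those in replicate 2, 69.3% overlapped a peak in replicate 1. The mean of these 2 directions was 60.9%, with an SD of 11.8. Both directions describe 1 pair of libraries, so this SD is no spread over replicates. Much of the gap between directions came from the length of the lists, since with equal numbers of peaks the shares were 64.6% and 66.0%. Shuffled peaks gave 1.86% ± 0.0337 and 2.42% ± 0.0369 (SD, 20 shuffles). Of the bases in a hotspot of either library, 53.0% lay in a hotspot of both, against 1.28% for shuffled hotspots. The hotspots of replicate 2 lay largely within those of replicate 1, with 88.0% of their bases shared, whereas 57.1% of the bases of replicate 1 were shared. Among the higher-scoring 50% of each list the mean share of peaks found in the other library was 77.5%.

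Recovery rose with the score of the peak. In the lowest decile 8.39% of the peaks of replicate 1 and 10.6% of those of replicate 2 overlapped a peak in the other library, and in the highest decile 95.9% and 97.2% did. Of the highest decile, 99.98% of peaks in replicate 1 and 100% in replicate 2 lay in a hotspot of the other library. Strong peaks that lay in neither a peak nor a hotspot of the other library numbered 5 of 20565 in replicate 1 and 0 of 15752 in replicate 2. Of these 5, 2 were on the mitochondrial genome, 2 on unplaced scaffolds, and the remaining 1 lay 1521 bp from the nearest TSS of Hoxb5, a homeobox gene of the Hoxb cluster, at chromosome 11, positions 96301916 to 96302065, with a score of 105. With 1 library on each side these counts have no test, and they depend on how strength and absence are defined, since 129 and 10 peaks qualified in the top 20% and 872 and 453 when hotspots were not considered.

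**Figure D1:**
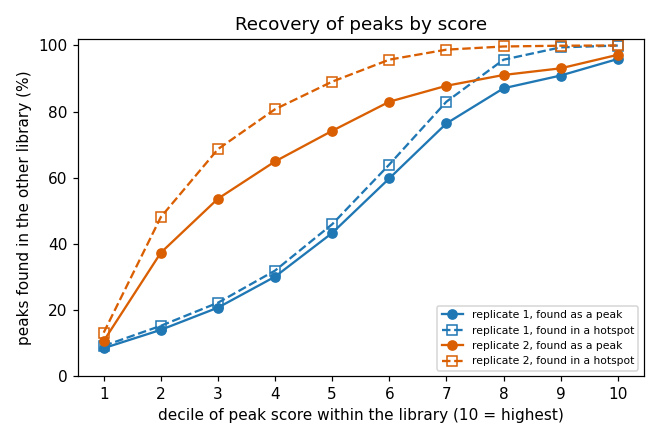
Percent of peaks found in the other library (vertical axis) by decile of the authors' score within each library (horizontal axis, 10 is the highest), for replicate 1 and replicate 2. Filled circles count overlap with a peak and open squares overlap with a hotspot, and the share found as a peak runs from 8.39% and 10.6% in the lowest decile to 95.9% and 97.2% in the highest.

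Promoters of protein-coding genes held 13.6% of peaks in replicate 1 and 16.9% in replicate 2, a mean of 15.2% ± 2.33 (SD, n = 2), whereas 1.48% of random windows of the genome lay there. With equal numbers of peaks the shares were 16.7% and 16.9%. Exons outside promoters held 5.75% ± 0.624 of peaks, introns 36.1% ± 1.33 and intergenic sequence 42.9% ± 1.62 (SD, n = 2). Random windows fell in these classes at 3.17%, 35.0% and 60.4%. Peaks found in both libraries were at promoters more often, 20.6% in replicate 1 and 20.4% in replicate 2, than peaks found in 1 library, of which 5.86% in replicate 1 and 8.97% in replicate 2 were. Among the higher-scoring 50% of each list the mean share at promoters was 26.3%.

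Genes of the developing nervous system had open promoters almost without exception. A promoter peak was present in both libraries for 26 of 26 neural progenitor genes, 25 of 25 dorsal patterning genes, 32 of 32 genes of postmitotic neurons and 23 of 23 genes of forebrain and midbrain, and in replicates 1 and 2 for 34 and 33 of 34 transcription factors of spinal neuron classes. Of 22 ventral patterning genes 21 had one in both libraries, and Dbx2, a homeobox gene of ventral progenitors, had none in either. Vsx1 had one in replicate 1 only. Among 19121 genes in no set, 73.2% in replicate 1 and 72.5% in replicate 2 had a promoter peak. All 6 of these lists were called above other genes by Fisher's exact test, with adjusted p from 0.000128 for spinal neuron class factors in replicate 1 to 0.0253 for ventral patterning. Housekeeping genes were also called, with 23 of 23 in both libraries (adjusted p = 0.00267, Fisher's exact test), as were ribosomal protein genes, with 73 of 76 in both, and zinc finger genes named Zfp, with 349 and 346 of 394. When random lists were matched on the GC content of promoters, 4 of these calls ended, those of ventral patterning, dorsal patterning, spinal neuron class factors and housekeeping genes, and the ventral call also ended within 200 bp of a TSS. Over all alternatives the highest adjusted p of these 4 sets was 0.695, 0.413, 0.142 and 0.0544, each in that permutation test, and the lowest was 0.00869, 0.000323, 3.54e-05 and 0.000721.

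Markers of blood, liver and immune cells had few promoter peaks. In the erythroid list 4 of 17 genes had one in both libraries, among them Epor, the erythropoietin receptor, Nfe2 and Tspan33 (adjusted p = 8.84e-05 and 0.000114, Fisher's exact test). In the myeloid and microglia list 2 of 16 had one, Cd68 and Mpo (adjusted p = 2.73e-06 and 3.44e-06, exact test). In the liver list 1 of 17 in replicate 1, Hnf4a, and 0 in replicate 2 had one (adjusted p = 4.48e-08 and 1.58e-09, exact test). In the lymphocyte list 3 and 2 of 16 had one (adjusted p = 3.04e-05 and 3.44e-06, exact test), with Foxp3 and Pax5 open in both libraries and Rag2 in 1. Pax5 is also a gene of the midbrain and hindbrain boundary.

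Lists of other cell types of the embryo were not called at promoters in the main comparison. Of the neural crest and peripheral glia list 18 of 20 genes had a promoter peak in each library (adjusted p = 0.171, Fisher's exact test). Of simulated lists of 20 genes with 90% of promoters open only 37.5% were called, so the lack of a call here does not show that there is no difference. Of the mesoderm and connective tissue list 23 and 24 of 26 had one, with Myf6, a muscle regulator, open in neither library, and the adjusted p was 0.171 and 0.0426 by the same exact test, so that replicate 2 alone passed. The list passed in both libraries when random lists were matched on promoter GC content (adjusted p = 0.0255 and 0.00269, permutation test, with a range of 0.00269 to 0.374 over its alternatives). Endothelial genes had 15 and 11 of 18, and Cdh5 and Eng, which encode surface proteins of endothelial cells, had none in either library. Late glial genes had 10 and 9 of 15, and Gfap, Mag, Mog and S100b were among those that lacked a promoter peak in both libraries. Heart and striated muscle genes had 9 and 8 of 15, and 6 of them lacked one in both, among them Myh6 and Myh7, the cardiac myosin heavy chains, Acta1, Ckm and Myl7.

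Few promoters were open in gene families of sensory organs, epithelia and detoxification. Of 1134 olfactory receptor genes 40 and 38 had a promoter peak, of 327 vomeronasal receptor genes 4 and 8, of 110 keratin and keratin-associated genes 14 and 13, of 42 beta-defensin genes 4 and 1, and of 100 Cyp genes 26 and 26. All 5 families were called below other genes by Fisher's exact test, with 4.54e-17 as the highest adjusted p, for beta-defensins in replicate 1. The Sox family had 19 and 18 of 19 open promoters (adjusted p = 0.00669 and 0.0584, exact test), and Fox had 38 of 44 in both libraries (adjusted p = 0.0920 and 0.0666). The remaining families of developmental regulators also missed the threshold, with 8 of 9 Pax, 10 of 10 Lhx and Lmx, 13 of 14 Nkx, 6 of 6 Irx and 17 of 19 Wnt genes open in each library, 10 and 11 of 13 Tbx, 19 and 18 of 22 Fgf and 10 and 9 of 12 Bmp genes. For the smallest families this decides nothing, because even with every promoter open the adjusted p was 0.107 in both libraries for Lhx and Lmx and 0.404 and 0.247 for Irx (Fisher's exact test). The clustered protocadherins, cell surface proteins of neurons, went in opposite directions, with 50 of 57 open in replicate 1 and 26 of 57 in replicate 2, above other genes in replicate 1 (adjusted p = 0.0194) and below them in replicate 2 (adjusted p = 6.55e-05, both by Fisher's exact test). Among the higher-scoring 50% of each list, and with equal numbers of peaks, they were below other genes in both libraries. Against random lists matched on promoter GC content they were a mean of 32.5 percentage points above (adjusted p = 0.000700 and 0.107, permutation test), so that their direction depends on the comparison.

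**Figure D2:**
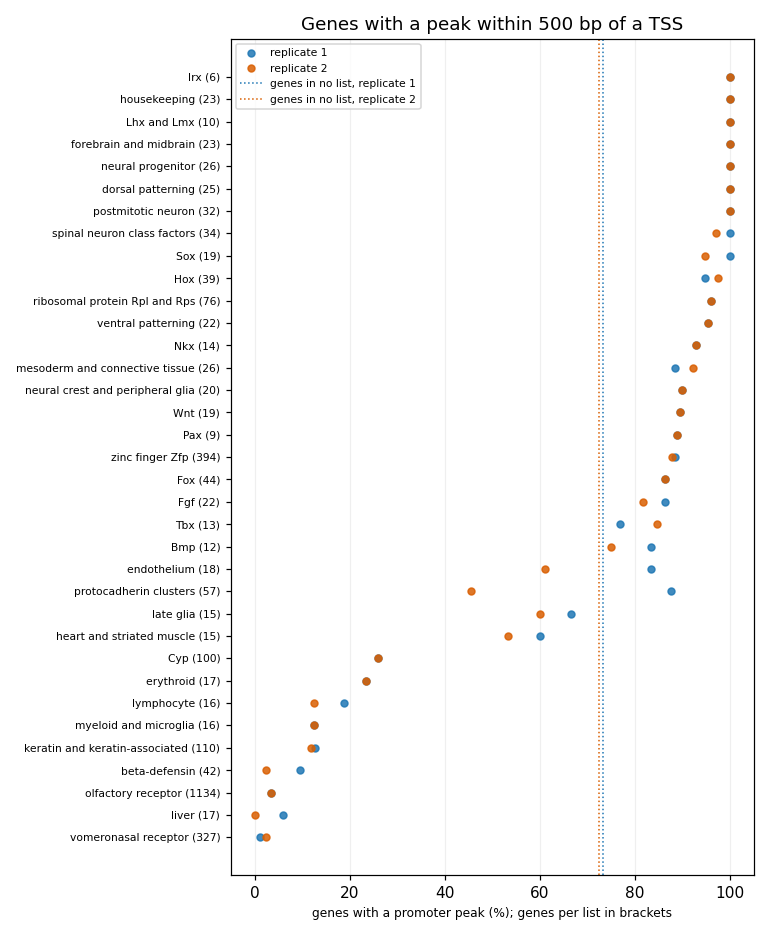
Percent of genes with a peak within 500 bp of a TSS (horizontal axis) for the 17 lists and 18 families (vertical axis, number of genes in brackets), with 1 point for each of the 2 libraries and dotted lines at the 73.2% and 72.5% of genes in no set. Olfactory receptors lie at 3.53% and 3.35%, and the neural progenitor list lies at 100% in both libraries.

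Regulators of neural tube patterning also collected distal peaks. Neural progenitor genes had 53.9 and 41.2 distal peaks per gene in replicates 1 and 2. This was 3.18 and 3.53 times the mean of random lists from the same deciles of territory length (adjusted p = 0.000823 in both, from 0.0002, the smallest p this permutation test can give). Territories still differed within a decile, so that Nr2f2, with 1305 kb, had the same expected count, 31.1 and 20.4, as the late glial gene Aqp4, with 287 kb. How much of the ratios comes from such differences was not tested. Nr2f2, an orphan nuclear receptor at chromosome 7, positions 70351944 to 70366735, had 206 and 159, Sox2, a transcription factor of neural progenitors at chromosome 3, positions 34650405 to 34652461, had 159 and 111, and Nr2f1 had 143 and 101. Ventral patterning genes had 2.25 and 2.60 times the random mean, led by Irx3 with 122 and 125 peaks, the floor plate factor Foxa2 with 91 and 48, and Nkx6-1 with 85 and 47. Dorsal patterning genes had 2.41 and 2.66 times the random mean, led by Pax3 with 113 and 67, Pax7 with 70 and 42 and the roof plate factor Lmx1a with 51 and 53. Genes of postmitotic neurons had 1.85 and 2.01 times the random mean (adjusted p = 0.00420 and 0.00300, permutation test), with Myt1l at 76 and 72, Ebf1 at 74 and 64 and Onecut1 at 81 and 44. Spinal neuron class factors had 2.73 and 2.84 times the random mean, with Foxp1 at 109 and 71, Lhx5 at 66 and 78 and Pax2 at 77 and 66. Forebrain and midbrain genes had 2.26 and 2.12 times the random mean, with Six3 at 110 and 60, Dmrta2 at 63 and 55 and Otx2, a regulator of the forebrain and midbrain, at 67 and 46. The forebrain and midbrain call ended when distal peaks had to lie over 5 kb from a TSS, and when hotspots replaced peaks.

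Lists of neural crest and mesoderm were called for distal peaks as well. The neural crest and peripheral glia list had 2.15 and 2.12 times the random mean (adjusted p = 0.00622 and 0.0150, permutation test), with Ets1 at 68 and 65, Tfap2a at 71 and 39 and Tfap2b at 89 in replicate 1 and 22 in replicate 2. The genes of this list had a mean of 24.5 and 17.2 distal peaks and a median of 8.5 and 9.5. The mesoderm and connective tissue list had 1.70 and 1.82 times the random mean (adjusted p = 0.0170 and 0.0122, permutation test), with Tbx15 at 71 and 48, Foxc1 at 58 and 48 and Pax1, a gene of the vertebral precursors, at 56 and 45, and this call ended in the same 2 settings as that of forebrain and midbrain. The endothelial list had 1.09 and 1.14 times the random mean, with Cdh5 at 55 and 33, Flt1 at 27 and 24 and Emcn at 22 and 22. For erythroid genes the ratios were 1.12 and 0.609, with Nfe2 at 8 and 2 and Tspan33 at 6 and 4. Myeloid genes had ratios of 1.68 and 1.66, late glial genes 1.44 and 1.58, liver genes 1.12 and 0.857, heart and striated muscle genes 1.64 and 1.38, lymphocyte genes 1.67 and 1.61 and housekeeping genes 1.45 and 1.47, and none of these lists was called. Among their genes Ptprc, the leukocyte antigen CD45, had 59 and 43 distal peaks, Apob 47 and 28, Cps1 48 and 17, Tbx5 54 and 38, Pax5 52 and 41, Slc1a3 30 and 30 and Eef1a1 25 and 12. These counts of single genes do not allow for territory, which was 1434 kb for Apob and 1034 kb for Cps1.

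Families of developmental regulators also had more distal peaks than random lists. Sox genes had 3.11 and 3.13 times the random mean of distal peaks, Pax genes 3.31 and 3.49, Nkx genes 3.51 and 3.18, Irx genes 2.49 and 3.43, Lhx and Lmx genes 2.67 and 3.26, Tbx genes 2.36 and 2.49, Fox genes 2.23 and 2.26 and Wnt genes 2.00 and 2.14, and all 8 families were called. The Tbx call ended when hotspots replaced peaks, and the Irx call when peaks were counted within 50 kb of a TSS. Fgf genes had ratios of 0.800 and 0.887, Bmp genes 1.11 and 1.47, ribosomal protein genes 1.32 and 1.25, Zfp genes a mean of 1.17, clustered protocadherins 0.779 and 1.01 and keratins 0.735 and 0.671, none of them called in both libraries. Other settings called 3 of these families. Protocadherins were below random lists within 50 kb of a TSS and without matching on territory, and keratins in these settings, in the higher-scoring 50%, with equal numbers of peaks and in replicate 2 alone. Zfp genes were above in the higher-scoring 50%, over 5 kb from a TSS and in replicate 2 alone, and below within 50 kb. Olfactory receptors had 0.226 and 0.225 times the random mean, vomeronasal receptors 0.129 and 0.230, beta-defensins 0.439 and 0.372 and Cyp genes 0.587 and 0.632, and these 4 were called below. Members of such families lie side by side in the genome, and when each list was moved as a block along the genome, an alternative chosen after seeing the data, all 4 of these calls ended while 17 sets were still called above. The mean ratios, 0.225 for olfactory receptors, 0.179 for vomeronasal receptors, 0.406 for beta-defensins and 0.610 for Cyp genes, could barely change by construction. They were still taken against genes in the same deciles of territory length, and the moved blocks entered only the p. The call of beta-defensins also ended over 5 kb from a TSS, where the ratios were still 0.513 and 0.455 (adjusted p = 0.0830 and 0.0521, permutation test). In the permutation test with blocks the highest adjusted p was 0.140 for olfactory receptors, 0.0513 for vomeronasal receptors, 0.478 for beta-defensins and 0.236 for Cyp genes, against a lowest adjusted p of 0.000389 for each over its other alternatives.

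Across the genome the most distal peaks belonged to Zfhx3, a homeobox and zinc finger gene, with 279 in replicate 1 and 199 in replicate 2, followed by Zfp608 with 267 and 169, Auts2 with 190 and 187, Nr2f2 with 206 and 159, Lrmda with 166 and 157, Rbfox1 with 174 and 114, Nav2 with 107 and 180, Bcor with 143 and 134, Tenm4 with 143 and 132, Gse1 with 144 and 126 and Sox2 with 159 and 111, the same mean of 135 as Gse1. This ranking does not allow for territory, which ran from 360 kb for Gse1 to 2318 kb for Rbfox1 among these genes. The distal peak with the best mean rank of score lay 1042 bp from the TSS of Mex3b, at chromosome 7, positions 82866216 to 82866365, with scores of 148 and 143, in intergenic sequence. The next lay near Zc3h4 and Zmiz1, at 1056 bp and 1533 bp from a TSS, and others near Cct8l1, Gm42906, Igf2bp3, Limd1, Tmco5 and Chd2, between 3134 bp and 97143 bp away.

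**Figure D3:**
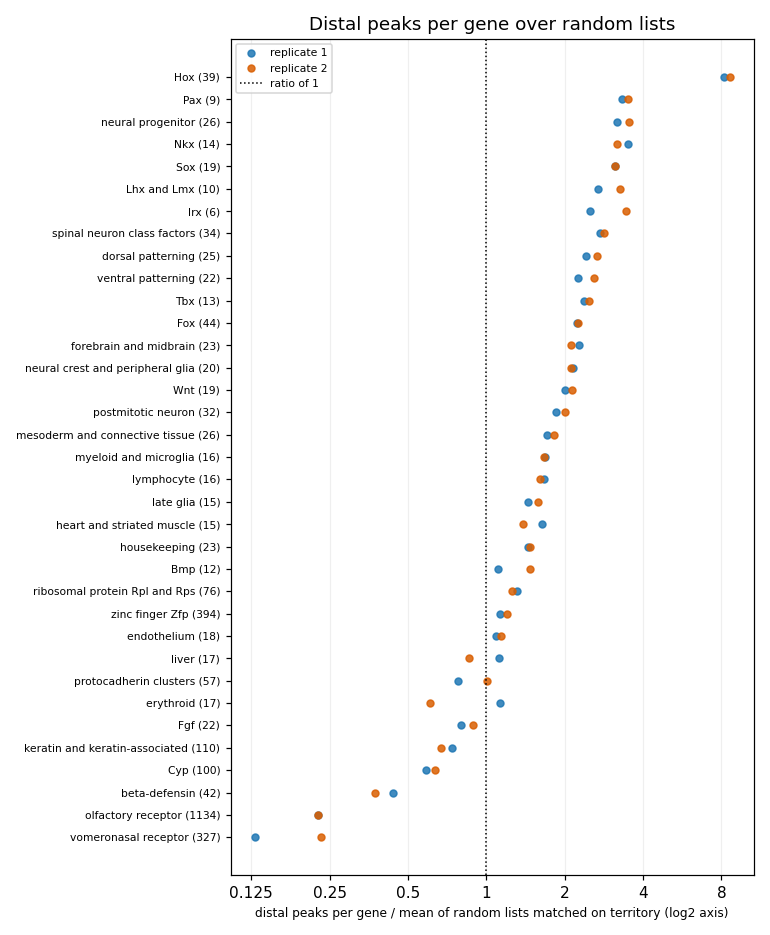
Distal peaks per gene divided by the mean of random lists matched on territory length (horizontal axis, log2 scale) for the 35 sets (vertical axis, number of genes in brackets), with 1 point for each of the 2 libraries. Hox genes lie at 8.18 and 8.61 and vomeronasal receptors at 0.129 and 0.230.

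The Hox genes, homeobox genes that set position along the body axis, had 8.18 and 8.61 times the distal peaks of random lists matched on territory, the highest ratio of the 35 sets in that comparison. Without matching on territory the ratio was 1.89 and 2.33, still called but with the lowest mean, 2.11, of the 17 sets called above, which Irx led with 10.6. A promoter peak was present at 37 and 38 of 39 Hox genes (adjusted p = 0.00192 and 0.000240, Fisher's exact test). When the list was moved as a block along the genome, an alternative chosen after seeing the data, the distal call held and the promoter call ended in replicate 1. The adjusted p was 0.0557 and 0.0121 at promoters by that permutation test, and over all alternatives it ran from 3.72e-05 to 0.0557. Hoxc4 had 49 and 56 distal peaks and Hoxb13 59 and 42. Hotspots covered 55.3% of the Hoxa cluster on chromosome 6 in replicate 1 and 71.5% in replicate 2, and 45.7% and 68.0% of the Hoxd cluster (chromosome 2, positions 74668310 to 74765142). For Hoxb (chromosome 11, positions 96194316 to 96368256) the cover was 47.0% and 30.8%, and for Hoxc (chromosome 15, positions 102921103 to 103036852) 43.8% and 30.7%. Replicate 1 also covered 1.54 times as much of the whole genome as replicate 2. As whole clusters, Hoxb and Hoxc lay close to that, at 1.53 and 1.43, and Hoxa and Hoxd departed from it, at 0.773 and 0.672. Genes within each cluster went both ways. Hoxc9, Hoxc10, Hoxc11, Hoxc12 and Hoxc13 were covered more in replicate 1, with Hoxc11 at 73.6% and 24.4% in replicates 1 and 2. Hoxc4, Hoxc5, Hoxc6 and Hoxc8 were covered more in replicate 2, with Hoxc6 at 26.3% and 62.1%. Promoter peaks were lacking in replicate 1 at Hoxd11 and Hoxd12 and in replicate 2 at Hoxc12.

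**Figure D4:**
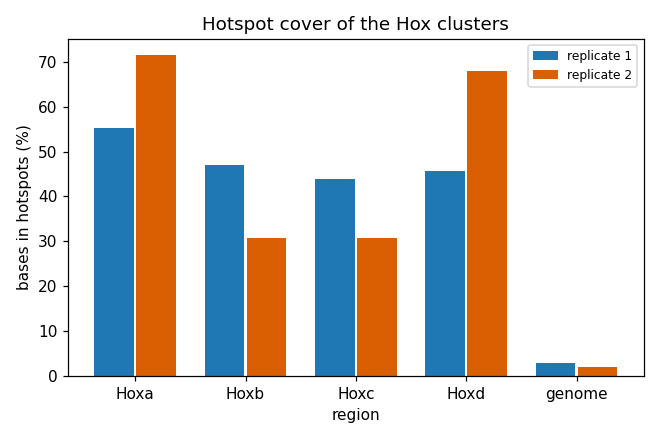
Percent of bases in hotspots (vertical axis) in the 4 Hox clusters and in the genome (horizontal axis), as bars for the 2 libraries. Hoxa and Hoxd are covered more in replicate 2, whereas Hoxb, Hoxc and the genome, at 2.97% and 1.92%, are covered more in replicate 1.

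Binding motifs of known factors were sought in the peaks. In distal peaks 17 of 34 consensus motifs were over-represented in both libraries against GC-matched windows. The motif of CTCF, an insulator protein, was in 4.01% of distal peaks in replicate 1 and 4.59% in replicate 2, 89.6 and 76.9 times the share in windows. The motif of REST, which represses neuronal genes in other cells, was in 304 and 272 distal peaks and in 3 and 1 windows, a ratio with intervals of 34.3 to 494 and 48.4 to 10782. RFX motifs had ratios of 26.0 and 26.9 and NFI motifs 14.3 and 11.2. Motifs of homeodomain factors were called too, with ratios of 3.51 and 3.19 for HOX-PBX, 2.01 and 2.11 for the homeodomain core and 1.81 and 1.98 for POU, and so was PAX6 with 3.50 and 2.86, from 35 and 20 peaks, though not when windows were also matched on the number of CpG dinucleotides. The CAGCTG E-box, bound by basic helix-loop-helix factors, was in 15.7% and 17.1% of distal peaks, with ratios of 1.81 and 1.73, whereas the CAGATG E-box had 1.33 and 1.33 and was not called. The SOX motif had 1.66 and 1.49, just short of the threshold in replicate 2, and it was called when repeats were left out, when windows were matched on CpG too, and among the higher-scoring 50% of peaks. The GATA motif, bound by blood cell factors among others, was less frequent in distal peaks than in windows, at 0.772 and 0.802 (adjusted p = 1.09e-18 and 7.28e-10, Fisher's exact test). Against windows 1 kb from each peak, where mean GC content was 44.2% and 45.0% against 50.2% and 52.9% in the peaks, the calls for HOX-PBX, POU, homeodomain and MEF2 ended, and the mean ratio was 0.691 for homeodomain and 0.749 for MEF2, whose ratios against GC-matched windows were 2.04 and 2.74.

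In promoter peaks 18 of 34 motifs were over-represented. ETS motifs were in 3.35% and 3.52% of promoter peaks, 26.7 and 24.7 times the share in windows. NRF1 motifs had ratios of 41.0 and 59.2, YY1 17.8 and 13.1, CREB-ATF 9.70 and 9.98 and NFY 6.34 and 7.71, the last in 7.25% and 7.44% of promoter peaks. SP-KLF motifs were in 11.3% and 12.4%, with ratios of 2.81 and 2.84. The REST motif was in 34 and 30 promoter peaks and in 0 windows (adjusted p = 3.41e-10 and 5.02e-09, Fisher's exact test). AT-rich motifs depended on the background, since against windows 1 kb from the peak the mean ratio of homeodomain, HOX-PBX, FOX, MEF2 and POU fell below 1, to 0.189, 0.368, 0.539, 0.419 and 0.803. The promoter calls for FOX, HOX-PBX and homeodomain also ended when windows were matched on CpG.

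**Figure D5:**
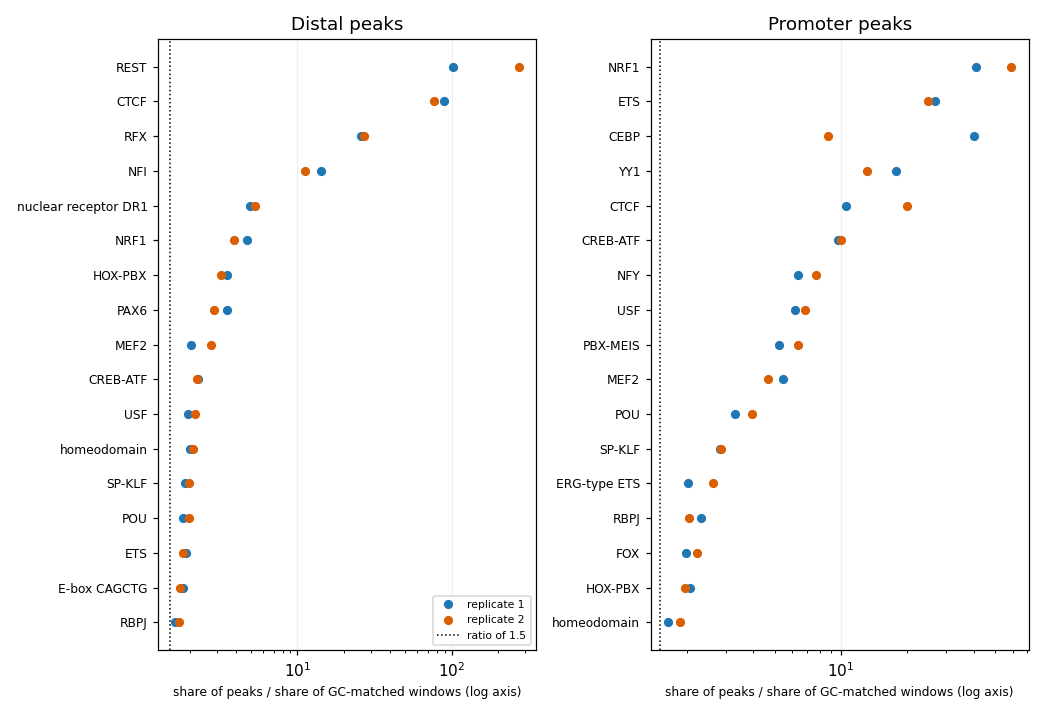
Ratio of the share of peaks with a motif to the share of GC-matched windows (horizontal axes, log scale) for the motifs over-represented in distal peaks (left) and promoter peaks (right), with 1 point for each of the 2 libraries and a dotted line at 1.5. REST and CTCF lead in distal peaks and NRF1 in promoter peaks, where REST is not drawn because no window held its motif.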

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

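The tests of hotspot cover in dense runs of peaks and the 3 tests on the Hox clusters were set before their values were seen, and the other tests in this part were chosen only after the result was seen. The labels give 1 group, so no biological explanation from the design was tested.

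Peaks outside the main chromosomes entered the overlap of peaks but not the comparisons of location, genes or motifs. They are listed because those comparisons left them out, and no test was run on their counts. The mitochondrial genome held 30 peaks in replicate 1 and 29 in replicate 2, and unplaced scaffolds held 212 and 321.

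Peaks found in 1 library only numbered 94571 in replicate 1 and 47428 in replicate 2. They were rarer at high scores. Of the highest decile 95.9% and 97.2% overlapped a peak and 99.98% and 100% a hotspot of the other library. Peaks close to the calling threshold would give this pattern for most of them. In the top 10% by score 872 and 453 overlapped no peak of the other library, but all except 5 and 0 of these lay in its hotspots. GC content may contribute, since at equal score peaks of replicate 2 only were on average 2.53 percentage points higher in GC than its shared peaks, in all 10 deciles, and peaks of replicate 1 only were lower in 9 of 10 deciles. The exception was decile 9 of replicate 1, where they were 2.97 points higher. In decile 10 the difference was 0.342 points in replicate 2 and -0.478 in replicate 1, with standard errors of 0.415 and 0.354, so neither was clear of 0. The gaps of replicate 2 were largest in deciles 8 and 9, at 4.08 and 6.04 points. There 99.7% and 99.9% of peaks lay in a hotspot of replicate 1, so these gaps concern where peaks were called within hotspots of both libraries. Both explanations stay open together, as do a difference in depth and any difference between the tissue samples, which were not tested.

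Runs of peaks much denser in 1 library were taken as the 10 windows of 250 kb with the largest excess in each library, and the genes named for them were chosen after their values were seen. In replicate 1 these lay near Tfap2b (114 against 25 peaks), Cdkn2a (73 against 15) and Gata3 (71 against 23) among others. The median score lay under the 20th percentile of the list in 2 windows, near Adamts18 and Tbl1xr1. The other 8 ran from a median score of 32.5 near Cxcr4 to 69 near Hoxc13, shared peaks included. The median was 45 over all peaks of replicate 1 and 32 over those found in replicate 1 only. Weak peaks also lie above this cut, since 20.7% of peaks in decile 3 of replicate 1 overlapped a peak of replicate 2. The cut therefore decides nothing about weak peaks in these 8 windows. In replicate 2 the windows lay near Alpk3 (80 against 25) and Hs1bp3 (107 against 46) among others. There 9 windows had a median under the 20th percentile, which weak peaks admitted by the caller would give. Hotspots of the other library covered the windows at a median of 0.733 times its genome for the runs of replicate 1, from 0.0934 to 3.62 at Hoxc13, and 2.34 times for those of replicate 2, from 0.504 to 3.85. This decides nothing, because the windows were picked by peak counts and 100% of peaks lay in a hotspot of their own library, so whether the regions are as open in the other library stays open.

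The Hox clusters were balanced differently, with Hoxa and Hoxd covered 0.773 and 0.672 times as much in replicate 1 as in replicate 2, whereas Hoxb and Hoxc, at 1.53 and 1.43, lay close to the 1.54 of the genome. These ratios are for whole clusters, and genes within each cluster went both ways. The odds ratio of Hoxa and Hoxd against Hoxb and Hoxc peaks, replicate 2 over replicate 1, was 1.62 with all peaks and 1.48 in the higher-scoring 50% of each list, between the bounds of 1.2 and 1.5 set for weak peaks or the length of the lists. With equal numbers of peaks it was 1.57 and by hotspot bases 2.05, both past 1.5, but the interval of 1.24 to 2.01 for equal numbers, from counting error alone, includes that bound. Hoxa and Hoxd were 0.712 percentage points richer in GC, less than the 2 points that would have favoured GC content. Limb bud tissue in replicate 2 is a hypothesis from the activity of Hoxa and Hoxd genes in limbs, and a list of 22 limb bud genes, such as Hand2 (71 and 78 distal peaks in replicates 1 and 2), Msx2 (57 and 44) and Tbx5 (54 and 38), lay at the 88.8th percentile of random lists for the ratio of replicate 2 to replicate 1, short of the bound set. Of these genes 3 are also in the neural lists and 9 in the mesoderm or heart lists, and weak peaks, GC content and limb bud tissue cannot be told apart because the value set for each fell between its bounds.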

How the results depend on the processing

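The alternatives that moved lists as blocks along the genome or matched windows on CpG count were chosen only after the results were seen, and the others were planned. Of 80 alternative values for 15 main results, 61 kept within the spread or within 1.5 times the count and 19 moved. This tally is no measure of stability. For the share of peaks found in the other library and the share at promoters, the values entered for each library alone are those behind the SD. They always lie within that SD, so they could not move. Shared hotspot bases have 1 value for the pair of libraries and so no spread between libraries. No paired analysis was possible because there is only 1 group, and the unknown depth limits any reading of differences in list length. The REST motif at promoters has no ratio, since no window held it. The cause was not tested for any change below except where a wider or stricter definition makes it by construction.

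The share of peaks found in the other library was 77.5% in the higher-scoring 50%. The values of 52.6% and 69.3% entered for each library alone are the directions of the main overlap. That overlap needs both libraries, so it was not tested with a library left out. Shared hotspot bases were 56.0% in the higher-scoring 50%, 54.2% with equal numbers and 53.0% on autosomes, against 53.0% in the main result. The share at promoters was 20.5% within 1000 bp of a TSS, 11.004% within 200 bp, 26.3% in the higher-scoring 50%, 11.5% with 1 TSS per gene, and 13.6% to 16.9% with each library alone. By hotspot, recovery was 9.08% and 13.1% in the lowest decile and 99.98% and 100% in the highest. Strong peaks in 1 library numbered 1 in replicate 1 with the top 5%, 129 and 10 with the top 20%, and 872 and 453 by absence of a peak only. Sets with fewer distal peaks numbered 7 when peaks were counted within 50 kb and 0 when lists were moved as blocks. With each library alone the counts were 11 to 12 sets above and 9 to 10 below at promoters, 17 to 18 with more and 4 to 5 with fewer distal peaks, 19 to 20 distal motifs and 19 to 19 promoter motifs.

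Among single sets and motifs 43 values changed direction, most of them without a call. Against windows 1 kb from the peak the mean ratio was 0.691 for homeodomain and 0.749 for MEF2 in distal peaks. In promoter peaks it was 0.803 for POU, 0.189 for homeodomain, 0.368 for HOX-PBX, 23.3 for RFX, 0.613 for TEAD, 0.539 for FOX, 0.654 for AP-1, 0.419 for MEF2, 0.625 for SRF, 0.433 for HNF4 and 0.353 for RUNX. Matched on CpG, promoter ratios were 1.21 for TCF-LEF, 0.747 for FOX, 1.31 for GATA and 0.999 for SRF. With repeats left out they were 0.803 for the CAGCTG E-box, 0.911 for AP-1 and 0.911 for RUNX, and in the higher-scoring 50% 1.18 for RFX and 1.09 for TCF-LEF. Without matching on territory the distal ratio was 0.678 for lymphocyte, 0.704 for housekeeping, 1.41 for Fgf, 0.961 for Zfp and 0.853 for ribosomal protein genes. Over 5 kb from a TSS it was 1.14 for liver and 1.29 for protocadherins, and within 50 kb 1.23 for Fgf and 0.839 for Zfp. Replicates 1 and 2 alone gave 1.12 and 0.609 for erythroid genes, 1.12 and 0.853 for liver genes, and 0.776 and 1.01 for protocadherins. At promoters the difference from other genes in percentage points was 0.571 for endothelium within 1000 bp and -0.928 for Tbx within 200 bp, and 4.15 for endothelium with lists moved as blocks. With lists matched on GC it was 3.26 for endothelium, -3.64 for Fox, -4.41 for Wnt and 32.5 for protocadherins, and replicates 1 and 2 alone gave 10.1 and -11.4 for endothelium and 14.5 and -26.9 for protocadherins. Of the other values for single sets, motifs and genes, 1083 stayed, 33 lost and 45 gained a call, and 217 counts of distal peaks were tallied as moved. A count was so tallied unless it changed by less than the SD between libraries. Where that SD was 0, unchanged counts are therefore among them, such as the 0 distal peaks of Cd68 over 5 kb from a TSS.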

Other observations

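No test was run in this part, and the genes named in it were chosen after their values were seen.

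Several markers had a promoter peak in 1 library and not in the other. Sox10 and Avil of the neural crest and peripheral glia list, Myf5, Myog and Tbx6 of the mesoderm list, and Emcn, Erg, Icam2, Robo4, Tek and Vwf of the endothelial list were among them. Mobp of the late glial list and Nppa, a natriuretic peptide of the heart, were open in 1 library as well.

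Single Hox genes differed more than their clusters. Hotspots covered 87.6% of Hoxc13 in replicate 1 and 0% in replicate 2, where the promoter peak, with a score of 90, lay just upstream of the gene. At Hoxd12 the cover was 4.42% and 91.6% and at Hoxa11 10.4% and 91.9%. Other windows with an excess in replicate 2 lay at Bmp7, a signal of the dorsal neural tube, with 43 and 103 peaks in replicates 1 and 2, and at Nectin1 with 42 and 92, but both hold mostly weak peaks, with median scores at the 12.4th and 6.37th percentile of the list. On the X chromosome replicate 1 had 4863 peaks and replicate 2 had 3601, and on the Y chromosome 62 and 87.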
